A study of Prunus incisa with 6 samples.

How the data were processed

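RNA was measured in 6 libraries of the cherry Prunus 'Gotenba zakura': 1 of bark and 5 of aerial roots of increasing length (0-1, 1-2, 2-4, 4-7 and over 7 mm). Per the labels, RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. The submitters' processing notes name Trimmomatic for read trimming. The assembler, the aligner, the counting tool, their versions and any genome build were not given in the sources used here. The unigene identifiers have the form that Trinity gives to de novo assembled transcripts. No genome was used here, and unigenes were given no chromosome positions.

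The deposited count table holds estimated counts (expected counts) that the authors made from the trimmed reads without further normalization, as decimals, for 113167 unigenes. The deposited FPKM table holds FPKM values that the authors scaled by unigene length and by a factor for each library, for the same unigenes. After division by the count totals, the ratio of count to FPKM in bark was 0.952 of that in the 0-1 mm roots (13263 unigenes compared). In the other root libraries it was between 1.006 and 1.01, so the factors follow the count totals closely but not exactly. Both tables carry the annotation made by the authors, with a Swiss-Prot description for 56521 unigenes, an NR description alone for 30293 and none for 26353. Counts were rounded to whole numbers before the tests. The library totals are the sums of the deposited counts, between 15290475 and 23803729.

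Each unigene was classed by the organism of its best database hit: Rosaceae (called host), other land plant, fungus, other organism or no hit, with 810 genera classified by hand. The host class rests on best hits and not on a genome. Shares of counts carry 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

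Tests used edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, unigenes with a total of at least 30 counts) in R 4.3.3, with a term for root against bark and a term for the centred order of the length classes. This leaves 3 residual degrees of freedom among the 5 root libraries. The lone bark library fits itself and is assumed to vary like the root libraries, and the p-values of roots against bark rest on that assumption. The length trend is tested among the root libraries. A Benjamini-Hochberg adjusted p under 0.05 was the threshold. The aerial root value is the fitted mean over the 5 root libraries, and the trend is the log2 change per length class. Errors of log2 values are standard errors derived from the fit. Group means of CPM, counts scaled to the library's size and TMM factor, carry the SD over the 5 root libraries. Single libraries were compared without a test, counting unigenes at least 4-fold apart with at least 5 CPM in the higher library and 0.5 CPM added to each value.

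The design, the tests, the alternatives, the 30 gene lists and the rule for named genes were set before the data were examined. The lists were defined by patterns on the Swiss-Prot description, or on the NR description where there was none: early auxin response, auxin perception and response factors, auxin transport, cytokinin, ethylene synthesis and signalling, ERF transcription factors, anaerobic response, gibberellin, abscisic acid, jasmonate, root founding and meristem regulators, mitotic cell cycle, DNA replication and histones, cell wall loosening, xylem and secondary wall, lignin and phenylpropanoid, suberin and periderm, flavonoid and anthocyanin, photosynthesis, phloem, root cap and root hair, cytosolic ribosome, defence proteins, heat shock, reactive oxygen, aquaporins, sugar and starch, circadian clock, dormancy and cold storage, and reference genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, on log2 CPM with a prior count of 2. Patterns match words, so a few members fall in a list by spelling. The list of clock genes holds a flavin monooxygenase for that reason.

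Named genes were, for each comparison, the 10 with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 5 CPM and an informative description, 1 per description. Where too few passed, the smallest unadjusted p filled the places. From each list, the member with the highest mean CPM and the members with the largest rise and fall past the threshold were added.

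The fits on host unigenes alone, with library sizes and TMM factors recomputed, and the same naming rule within host unigenes were chosen after seeing the composition of the bark library. The TMM factor of the bark library was 0.641 over all unigenes and 1.02 over host unigenes. The common dispersion was 0.223 over all unigenes and 0.0606 over host unigenes. A fold against a group at 0 is given against a floor of 3 counts per library. Ratios with 1 to 3 counts in bark carry a 95% counting interval.

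The alternatives tried were RLE scaling, no filter, a filter of at least 10 counts in at least 2 libraries, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with 1 or 0.1 added, leaving out unigenes with a non-plant best hit or the photosynthesis list, summing counts by description, a log2 fold of at least 1, no length term, the lower bound of the class in mm, the root libraries without bark, leaving out each root library, and thinning the root libraries at random to the total of the bark library (chosen after seeing the data). The trend was recomputed under the 60 distinct orders of the 5 root libraries. Pathway counts from the deposited KEGG terms used a one-sided Fisher's exact test on host unigenes, over pathways of at least 10 unigenes. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

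The tests were tested on simulated data with 200 changed genes. At a 4-fold root against bark difference, 61.2% were called over all unigenes and 80.6% over host unigenes. At a 4-fold difference over the 4 length steps, 40.3% and 89.6% were called. Between 0 and 5.81% of calls were false. Apart from the planted changes, the simulation drew bark from the same mean levels and dispersion as the roots. It therefore cannot show how many calls are false given the fungal counts of bark or an unlike spread in bark.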

Results

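Transcript levels were measured in bark and in aerial roots of the cherry Prunus 'Gotenba zakura', a flowering cherry that forms roots above ground. There were 6 libraries and no replicates: 1 of bark and 1 for each of 5 aerial root lengths, 0-1, 1-2, 2-4, 4-7 and over 7 mm. The total of the estimated counts was 15290475 in bark and 23258423, 23803729, 23587269, 23535775 and 23635984 in the roots, from the shortest to the longest. Unigenes with a best hit in Rosaceae (host unigenes) held 29.3% of the bark counts (29.3 to 29.4%, 95% Wilson interval) and 94.2, 95.5, 95.7, 96.3 and 95.9% of the root counts. Unigenes with a fungal best hit held 46.4% in bark (46.4 to 46.5%) and 0.442, 0.316, 0.363, 0.156 and 0.194% in the roots. No 95% interval of these shares reached further than 0.025 percentage points from its value, for counting error only. By best hit, the fungal genera with the largest shares of all bark counts were Lophiotrema with 11.3%, Microthyrium with 8.76% and Diaporthe with 4.65%.

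**Figure D1:**
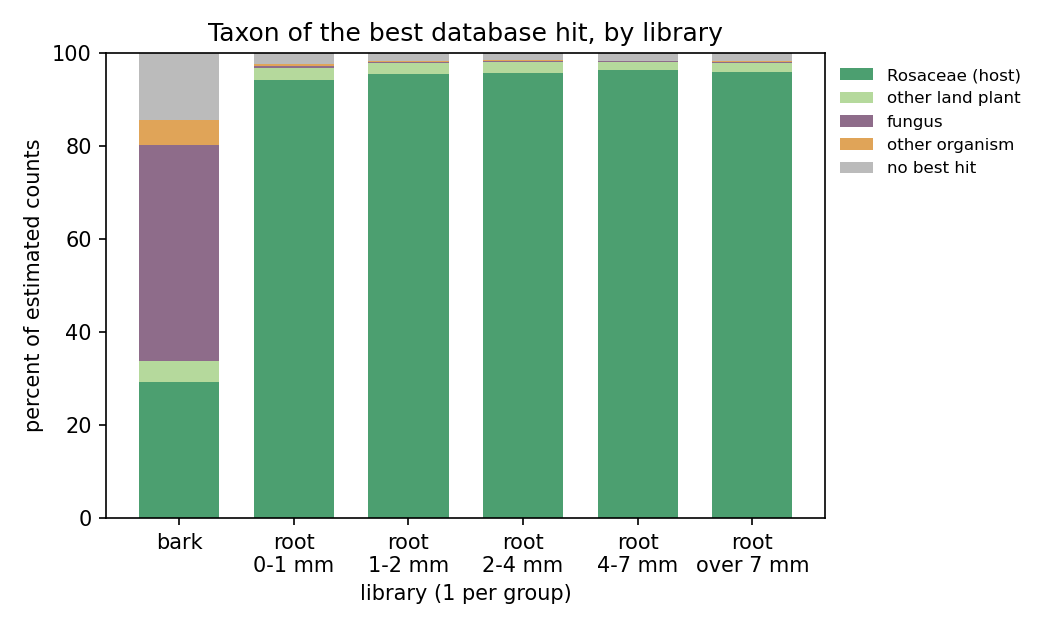
Percent of the estimated counts of each of the 6 libraries (1 per group) by the organism of the best database hit. Host unigenes held 29.3% of the counts in bark and between 94.2 and 96.3% in the aerial roots.

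The first comparison asked which genes differ between aerial roots and bark. Over all unigenes, most of the lower calls fell on unigenes with a fungal best hit and most of the higher calls on host unigenes. Among the largest rises, the wound-type proteinase inhibitor CEVI57, a protein that blocks digestive proteases, had 0 counts in bark and 28.1 ± 23.02 CPM in roots (SD, n = 5), at least 89.0-fold higher. The Myb factor MOF1, a regulator of floral organ number, also had 0 counts in bark and 11.9 ± 1.86 CPM in roots, at least 37.6-fold higher. Both bounds hold only in the scaling over all unigenes, and the bound for MOF1 was lower in the fit of host unigenes. Among the unigenes named by the rule, the largest fall was that of an elsinochrome reductase 1. This enzyme of a fungal toxin pathway had its best hit in a fungus and was at least 965.5-fold lower in roots. Of 90370 unigenes tested with edgeR, 12306 were higher in roots and 58141 lower, and with RLE scaling 4775 were higher and 60059 lower. Host unigenes made up 1.04% of the lower calls and fungal ones 64.0%. The scaling moved the median log2 difference of host unigenes, which was 0.93 with TMM over all unigenes, 0.24 with RLE over all unigenes, 0.08 with TMM over host unigenes and 0.05 with RLE over host unigenes. The values that follow are therefore relative to the other host unigenes, in fits of host unigenes alone that were chosen after seeing the data.

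Among host genes, the largest rises in aerial roots included Flowering-promoting factor 1, MOF1 and phosphoinositide phospholipase C 4, and the largest falls included pyruvate decarboxylase 4 and threonine dehydratase. Flowering-promoting factor 1, a small regulator of growth and flowering, rose from 0.874 CPM in bark to 36.1 ± 19.9 CPM in roots (log2 5.24 ± 0.66, SE, edgeR adjusted p = 0.0133). MOF1 was at 0 in bark and at 13.7 ± 2.21 CPM in roots, at least 20.8-fold higher. Phosphoinositide phospholipase C 4, which cleaves a membrane signalling lipid, had 1 count in bark and was 55.1 times as high in roots (counting interval 9.88 to 2175). Pyruvate decarboxylase 4, which starts ethanol fermentation, fell from 343.6 CPM in bark to 0.126 CPM in roots (log2 −11.44 ± 0.26, edgeR adjusted p = 0.000374). A membrane pyrophosphatase, a vacuolar proton pump, had 45.7 CPM in bark and 0 counts in all 5 root libraries, at least 341-fold lower. Threonine dehydratase, an enzyme of isoleucine synthesis, fell from 477.7 to 0.210 CPM (log2 −11.33 ± 0.42), and the peroxisomal long chain acyl-CoA synthetase 7 fell from 188.1 to 0.0811 CPM. Of 22858 host unigenes tested with edgeR, 1511 were higher in roots and 1573 lower. Of the lower ones, 97 were under 0.5 CPM in every root library with at least 5 CPM in bark, and 41.2% of these had a best hit outside Prunus, against 2.07% of all host unigenes tested. The host class rests on best hits, so whether these 97 come from the host was not tested. Threonine dehydratase also had a root mean under 0.5 CPM (0.210 CPM). Pyruvate decarboxylase 4 (best hit in Prunus), the membrane pyrophosphatase (Fragaria) and long chain acyl-CoA synthetase 7 (Rosa) were among these 97. Without the 0-1 mm library 1595 were higher and 1688 lower, without the 1-2 mm library 2763 and 2408, without the 2-4 mm library 699 and 873, without the 4-7 mm library 139 and 347, and without the over 7 mm library 366 and 672. Of the 78 host genes named by the rule as past the threshold, 37 lost the call without the 4-7 mm library, 24 without the over 7 mm library, 16 without the 2-4 mm library, 7 without the 0-1 mm library and 2 without the 1-2 mm library.

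Of 21 aquaporins, the channels that carry water across membranes, 7 rose and 0 fell in roots (12 and 0 adjusted over the list alone). Their median log2 was 1.29, or 1.20 with unigenes at 0 in bark set to their bound (camera adjusted p = 0.00638 at the preset correlation, and adjusted p = 0.429 with an estimated correlation). The tonoplast aquaporin TIP2-2 rose from 16.6 to 154.7 ± 55.5 CPM (log2 3.18 ± 0.45, edgeR adjusted p = 0.0166). The most abundant one, PIP1-4, had 1274 CPM in bark and 3273 ± 1124 CPM in roots and did not pass the threshold (log2 1.29 ± 0.35, edgeR adjusted p = 0.0613). Of 30 jasmonate genes, which act in wound and defence signalling, 1 rose and 12 fell (4 and 14 adjusted over the list alone), with a median of −0.67 that was 0.18 with TMM and −0.51 with RLE over all unigenes (camera adjusted p = 0.00994 at the preset correlation, and adjusted p = 0.429 with an estimated correlation). The lipoxygenase LOX3-1 fell from 851 to 23.9 ± 6.88 CPM (log2 −5.16 ± 0.29) and the repressor TIFY 10A from 935 to 215.5 ± 10.2 CPM (log2 −2.12 ± 0.12). Of 21 dormancy and cold storage genes 0 rose and 6 fell (1 and 8 adjusted over the list alone), with a median of −1.29 (camera adjusted p = 0.0470, adjusted p = 0.478 with an estimated correlation and 0.0540 with counts summed by description, and fry adjusted p = 0.0944). Bark storage protein A, a seasonal nitrogen reserve, fell from 80.8 to 3.30 ± 1.28 CPM (log2 −4.63 ± 0.40).

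Early auxin response, auxin transport and ethylene genes were higher in roots as sets at the preset correlation, and auxin perception genes did not pass. The calls of these 3 lists were lost with an estimated correlation (camera adjusted p = 0.429 for each) and with counts summed by description (0.439, 0.121 and 0.946). The auxin repressor IAA14, which holds back lateral root founding, rose from 10.7 to 85.8 ± 15.7 CPM (log2 3.003 ± 0.36, edgeR adjusted p = 0.0118). The auxin carrier PIN-LIKES 1 rose from 1.31 to 36.5 ± 14.3 CPM (log2 4.71 ± 0.68). The auxin receptor TIR1 rose by a log2 of 1.68 ± 0.36, while auxin response factor 4 fell (log2 −2.61 ± 0.21). An ACC oxidase homolog, named for its similarity to the enzyme that makes ethylene, rose from 1.31 to 12.6 ± 3.37 CPM (log2 3.22 ± 0.37). The kinase CTR1, which represses ethylene signalling, fell from 326 to 48.3 ± 9.97 CPM (log2 −2.76 ± 0.25, edgeR adjusted p = 0.00674). Of 54 early auxin response genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.88, or 0.79 with the bound (camera adjusted p = 0.0470, 0.0951 without the 1-2 mm library and 0.0650 with best hits in Prunus only). Of 22 auxin transport genes 4 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.92, or 0.87 with the bound (camera adjusted p = 0.0270). Of 39 ethylene genes 9 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 1.17, or 0.35 with the bound (camera adjusted p = 0.0248). Of 28 auxin perception genes 2 rose and 4 fell (3 and 6 adjusted over the list alone), and the list did not pass with camera (adjusted p = 0.1997), while it passed downward with counts summed by description (camera adjusted p = 0.0282) and in fry (adjusted p = 0.00871). Its median of −0.12 differed in sign from its mean of 0.22 and became 0.73 with TMM and 0.04 with RLE over all unigenes.

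Flavonoid, phloem and reference genes passed the set test with roots higher at the preset correlation (camera adjusted p = 0.0470, 0.0270 and 0.0270). They did not pass with an estimated correlation (camera adjusted p = 0.458, 0.429 and 0.649) or with counts summed by description (0.116, 0.433 and 0.188). With best hits in Prunus only the flavonoid list did not pass (camera adjusted p = 0.0544), and in fry the reference list did not (adjusted p = 0.0645). An anthocyanidin reductase, which makes tannin units, rose from 11.1 to 109 ± 38.4 CPM (log2 3.26 ± 0.53, edgeR adjusted p = 0.0217), whereas a flavonol synthase fell from 1005 to 70.2 ± 39.9 CPM (log2 −4.05 ± 0.32). Of 45 flavonoid genes 12 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.80, or 0.73 with the bound. The phloem lectin PP2-A1 rose (log2 3.13 ± 0.40) and the sieve element protein SEOB fell (log2 −2.17 ± 0.45). Of 23 phloem genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 1.31, or 0.74 with the bound. Tubulin beta-1, a reference gene, rose by a log2 of 1.51 ± 0.26. Of 30 reference genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.55.

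Oxygen-shortage genes moved both ways, with pyruvate decarboxylase 4, one of the 97 host unigenes near 0 in every root library, lower in roots and alanine aminotransferase 2, which forms alanine during low oxygen, higher (from 76.2 to 269 ± 39.9 CPM, log2 1.81 ± 0.20, edgeR adjusted p = 0.00960). Sucrose synthase, which feeds sugar into metabolism, rose from 349.7 to 761 ± 102 CPM (log2 1.11 ± 0.19), and the low-oxygen factor RAP2-2 had 848 CPM in bark and 964.5 ± 117 CPM in roots without passing (log2 0.18 ± 0.20). Of 20 anaerobic response genes 2 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of 0.18 and a mean of −0.40 (camera adjusted p = 0.925). Of 65 ERF genes 5 rose and 8 fell (6 and 10 adjusted over the list alone), with a median of 0.27, or 0.06 with the bound (camera adjusted p = 0.950). Of 44 cytokinin genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), with a median of 0.35, or 0.13 with the bound (camera adjusted p = 0.232). Of 43 abscisic acid genes 3 rose and 3 fell (4 and 3 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.840). Of 33 gibberellin genes 3 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.01 that was −0.36 with the bound and −0.02 with RLE over host unigenes (camera adjusted p = 0.635). In fry the cytokinin and gibberellin lists passed upward (adjusted p = 0.0188 and 0.0417).

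The root founding, root cap, xylem, lignin, suberin and wall loosening lists did not pass with camera for roots against bark. In fry, which does not compare a list with other genes, root founding, root cap and wall loosening genes passed upward (adjusted p = 0.0167, 0.0219 and 0.0202) and xylem genes downward (adjusted p = 0.00871). SCARECROW, which patterns the root ground tissue, rose from 4.59 to 30.9 ± 15.6 CPM (log2 2.62 ± 0.57, edgeR adjusted p = 0.0392). The root cap factor SOMBRERO was 33.1 times as high in roots (counting interval 9.17 to 273, log2 4.90 ± 1.17, edgeR adjusted p = 0.0481). Laccase-15, a lignin and tannin oxidase, fell from 4851 to 459.9 ± 177 CPM (log2 −3.45 ± 0.28), and the wall protein COBRA-like 4 fell from 88.3 to 7.11 ± 4.52 CPM (log2 −3.88 ± 0.19). Phenylalanine ammonia-lyase 1, the entry to phenylpropanoids, rose from 202 to 607 ± 146 CPM (log2 1.57 ± 0.26), while a caffeic acid O-methyltransferase fell from 1989 to 139.8 ± 40.7 CPM (log2 −3.86 ± 0.24). Of 23 root founding genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 0.131, and 0.0437 without the over 7 mm library). Of 12 root cap genes 2 rose and 0 fell (2 and 1 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.251). Of 38 xylem genes 0 rose and 4 fell in both counts, over all host genes and adjusted over the list alone, with a median of −0.24 that was 0.62 with TMM and −0.08 with RLE over all unigenes (camera adjusted p = 0.106, and 0.0241 without the over 7 mm library). Of 66 lignin genes 11 rose and 6 fell (16 and 7 adjusted over the list alone), with a median of 0.12 and a set test that pointed down (camera adjusted p = 0.950). Of 28 suberin genes 2 rose and 3 fell in both counts, also adjusted over the list alone, with a median of −0.24 that was 0.61 with TMM and −0.08 with RLE over all unigenes and a mean of 0.02 (camera adjusted p = 0.499). Of 133 wall loosening genes 10 rose and 10 fell (11 and 11 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.598).

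Growth, stress, sugar and clock lists did not pass with camera in roots against bark. In fry, defence and sugar and starch genes passed upward (adjusted p = 0.0458 and 0.00871) and heat shock and clock genes downward (adjusted p = 0.0188 and 0.0193). Of 48 mitotic genes 7 rose and 1 fell (11 and 5 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.131, 0.0241 without the 1-2 mm library and 0.0298 without the over 7 mm library). Replication protein A 70 kDa rose (log2 2.70 ± 0.34) and histone H1 fell (log2 −2.42 ± 0.29). Of 47 DNA replication genes 10 rose and 5 fell (20 and 5 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.0542, 0.0386 without the 1-2 mm library, 0.0464 without the 4-7 mm library and 0.0241 without the over 7 mm library). Of 183 cytosolic ribosome genes 1 rose and 12 fell (0 and 7 adjusted over the list alone), with a median of 0.17 and a mean of −0.24 (camera adjusted p = 0.925). Of 58 photosynthesis genes 1 rose and 1 fell (0 and 0 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.1997, and 0.000145 without the 0-1 mm library). A 15.4 kDa heat shock protein, a chaperone, fell from 131 to 1.61 ± 0.982 CPM (log2 −6.56 ± 0.20, edgeR adjusted p = 0.000421). Of 64 heat shock genes 3 rose and 8 fell (6 and 8 adjusted over the list alone), with a median of 0.22 and a mean of −0.05 (camera adjusted p = 0.950). Of 106 defence genes 13 rose and 5 fell (17 and 5 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.172). Of 76 reactive oxygen genes 7 rose and 9 fell (11 and 12 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.846). Granule-bound starch synthase 1 fell from 1588 to 414 ± 64.1 CPM (log2 −1.94 ± 0.21), and of 70 sugar and starch genes 10 rose and 2 fell (17 and 5 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.134). Of 22 clock genes 1 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of −0.25 that was 0.60 with TMM and −0.09 with RLE over all unigenes (camera adjusted p = 0.137). None of the 9 host lists that passed with the preset correlation passed with the estimated one. Over all unigenes 23 lists passed, and 9 did so with the estimated correlation. The lists there also hold members from other organisms (the ribosome list has 3163 members, 183 of them host unigenes). Camera compared them with a background mostly of other organisms (median log2 −9.19 over all unigenes, 0.93 for host unigenes). A list rich in host members can pass upward for that reason alone. The dormancy list passed upward there (camera adjusted p = 0.00158) with a median of −0.76.

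The second comparison asked which genes follow the growth of the aerial roots from 0-1 to over 7 mm. No single gene passed the threshold. Those with the smallest p included cellulose synthases of the secondary wall, with higher values in longer roots, and the stress factors ERF109, DREB1B and ERF012, with lower values. Cellulose synthase A subunit 8, which makes secondary wall cellulose, had 1.03, 1.23, 4.25, 12.8 and 19.6 CPM from the shortest to the longest roots (log2 per step 1.19 ± 0.12, edgeR adjusted p = 0.117). Cellulose synthase A subunit 7 had 2.00, 1.62, 5.45, 18.6 and 28.2 CPM, and the fasciclin-like protein 11, found in secondary walls, had 1.63, 1.62, 4.39, 13.2 and 20.2 CPM. An ACC oxidase of the ethylene pathway had 28.8, 32.1, 39.3, 67.5 and 100.9 CPM (log2 per step 0.47 ± 0.06). In the other direction, ERF109, a wound and jasmonate response factor, had 33.0, 3.59, 0.177, 0.176 and 0 CPM (log2 per step −2.99 ± 0.24, edgeR adjusted p = 0.108). The cold and dehydration factor DREB1B had 80.0, 12.7, 4.34, 1.06 and 0.533 CPM (log2 per step −1.89 ± 0.12, edgeR adjusted p = 0.108), and ERF012 had 185, 29.5, 18.5, 7.79 and 4.27 CPM. In edgeR, 0 of 90370 unigenes passed and 6943 had an unadjusted p under 0.05, against 1404 rising and 1643 falling in DESeq2 and 720 and 752 in limma-voom. Among host unigenes 0 passed in edgeR, with 5269 at an unadjusted p under 0.05 and a smallest adjusted p of 0.108, against 693 rising and 957 falling in DESeq2 and 0 in limma-voom. Without the 1-2 mm library edgeR called 1813 host unigenes rising and 2127 falling, and without the 0-1, 1-2, 4-7 or over 7 mm library 1902, 8314, 2974 and 1758 host unigenes had an unadjusted p under 0.05. Over all unigenes 3677 had one without the 0-1 mm library and 3512 without the 4-7 mm library.

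**Figure D2:**
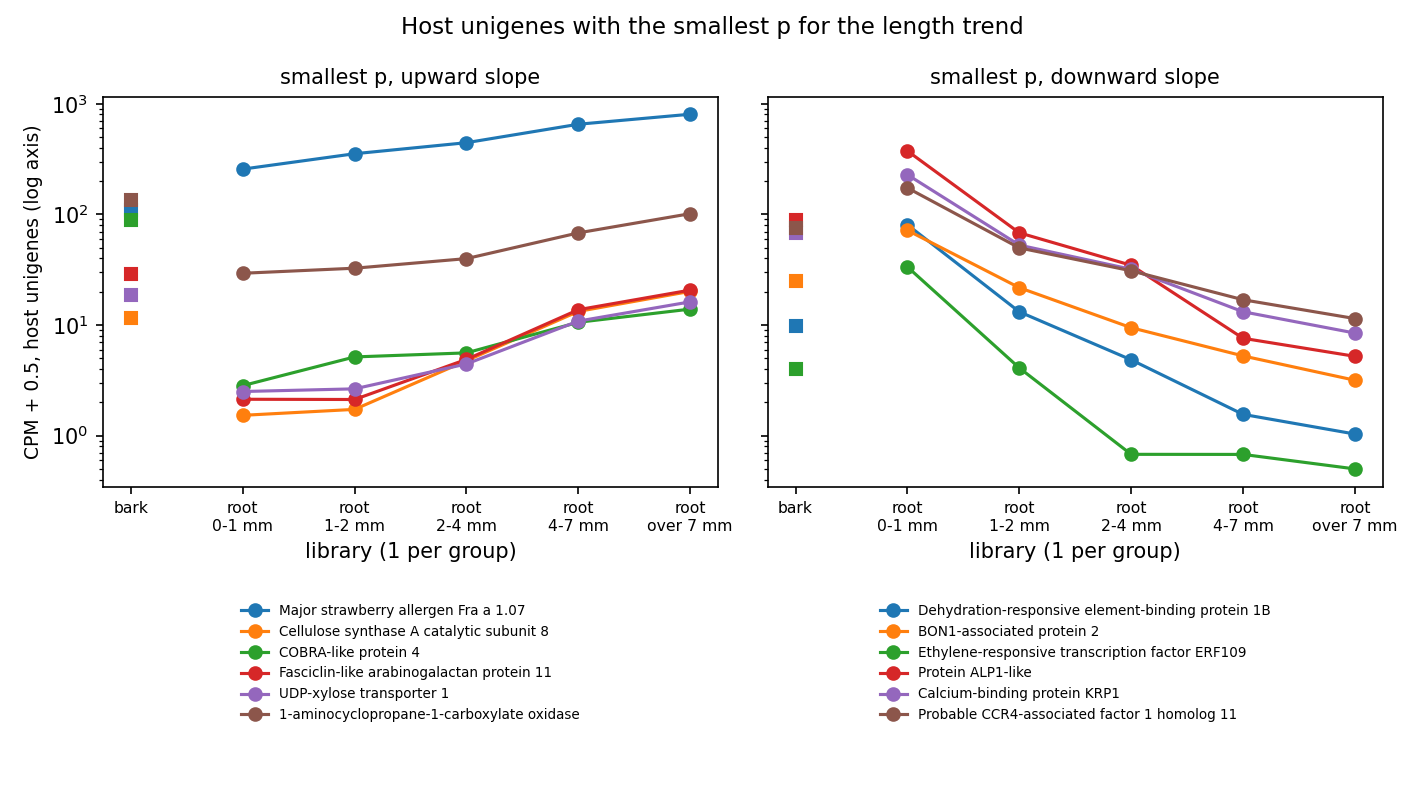
CPM of named host genes in each of the 5 aerial root libraries (1 per length class) and in bark, on a log axis. Cellulose synthase A subunit 8 goes from 1.03 to 19.6 CPM and ERF109 from 33.0 to 0 CPM from the shortest to the longest roots, and none passed the edgeR threshold.

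Ribosome and cell division genes were lower in longer roots as sets at the preset correlation. In fry the ribosome, mitotic and DNA replication lists did not pass (adjusted p = 0.109, 0.1003 and 0.0767). Of 183 cytosolic ribosome genes, the parts of the protein-making machinery, 0 passed over all host genes, and 2 rose and 148 fell adjusted over the list alone, with a median of −0.21 per step (camera adjusted p = 8.27e-24, and adjusted p = 0.482 with an estimated correlation). Of 48 mitotic genes 0 passed over all host genes, and 0 rose and 20 fell adjusted over the list alone, with a median of −0.22 (camera adjusted p = 6.01e-07, and adjusted p = 0.482 with an estimated correlation). Of 47 DNA replication genes 0 passed over all host genes, and 0 rose and 19 fell adjusted over the list alone, with a median of −0.14 (camera adjusted p = 6.01e-07, and adjusted p = 0.482 with an estimated correlation). Of 30 reference genes 1 rose and 10 fell adjusted over the list alone, with a median of −0.16 (camera adjusted p = 0.00422, adjusted p = 0.521 with an estimated correlation, and 0.0585 without the over 7 mm library). Elongation factor 1-alpha, a common reference gene, had 4761 CPM in the shortest and 2150 CPM in the longest roots (log2 per step −0.25 ± 0.08).

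**Figure D3:**
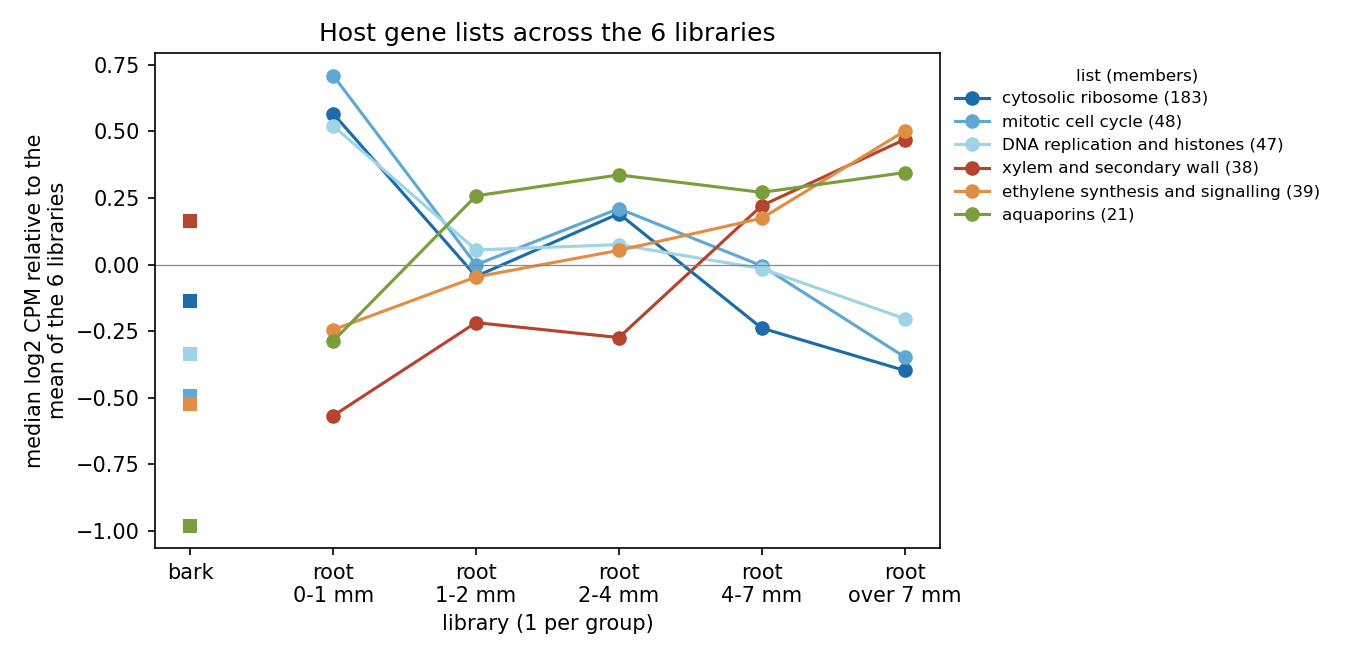
Median log2 CPM of the host members of 6 gene lists in each library, relative to the mean of the 6 libraries, with 1 library per group. The ribosome list has a median slope of −0.21 per length class and the xylem list one of 0.33.

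Xylem and ethylene genes were higher in longer roots as sets at the preset correlation. Of 38 xylem genes 0 passed over all host genes, and 14 rose and 0 fell adjusted over the list alone, with a median of 0.33 per step (camera adjusted p = 1.59e-07, and adjusted p = 0.204 with an estimated correlation). Of 39 ethylene genes 0 passed over all host genes, and 7 rose and 0 fell adjusted over the list alone, with a median of 0.22 (camera adjusted p = 9.04e-05, and adjusted p = 0.221 with an estimated correlation). Of 23 phloem genes 6 rose and 2 fell adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.0359, and adjusted p = 0.482 with an estimated correlation). Without the 1-2, 2-4, 4-7 or over 7 mm library the phloem list did not pass (camera adjusted p = 0.167, 0.0653, 0.0559 and 0.0585). Of 43 abscisic acid genes 2 rose and 1 fell adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.0159, adjusted p = 0.482 with an estimated correlation, 0.0952 without the 1-2 mm library and 0.345 without the over 7 mm library). Of 21 aquaporins 1 rose and 0 fell adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0159, adjusted p = 0.521 with an estimated correlation, and 0.604 without the 0-1 mm library). PIP1-4 had 1488, 3175, 3352, 3838 and 4511 CPM from the shortest to the longest roots. Of 58 photosynthesis genes 0 passed adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.00317, and adjusted p = 0.6998 with an estimated correlation). Without the 0-1 mm library the photosynthesis list went down with length (camera adjusted p = 2.29e-06).

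The other lists did not pass for length. ERF genes, many of them stress regulators, had a median slope of −0.05, with 3 rising and 15 falling of 65 adjusted over the list alone (camera adjusted p = 0.217). Anaerobic response genes had a median of −0.09, with 2 rising and 7 falling of 20 adjusted over the list alone (camera adjusted p = 0.186). Defence genes had a median of 0.08, with 11 rising and 9 falling of 106 adjusted over the list alone (camera adjusted p = 0.186). The allergen Pru av 1, a defence protein, had 928, 2742, 1763, 3600 and 5856 CPM from the shortest to the longest roots without passing. Adjusted over the list alone, 2 early auxin genes rose and 1 fell, 1 auxin transport gene rose and 3 fell, 3 cytokinin genes rose and 2 fell, 4 wall loosening genes fell, 2 suberin genes fell, 1 heat shock gene rose and 1 sugar and starch gene rose. The median slopes of these were 0.06, 0.07, 0.00, −0.06, −0.03, −0.00 and 0.03 (camera adjusted p = 0.484, 0.191, 0.946, 0.784, 0.946, 0.854 and 0.191), and the mean differed in sign for early auxin (−0.03), cytokinin (−0.02), suberin (0.01) and heat shock (0.04). Adjusted over the list alone, 0 genes passed for auxin perception, gibberellin, jasmonate, root founding, lignin, flavonoid, root cap, reactive oxygen, clock and dormancy genes. Their median slopes were 0.03, −0.01, −0.01, −0.05, 0.06, −0.04, 0.05, 0.07, 0.06 and 0.10 (camera adjusted p = 0.217, 0.659, 0.336, 0.729, 0.233, 0.831, 0.758, 0.119, 0.186 and 0.217), and the mean differed in sign for root cap genes (−0.04). The slopes of gibberellin, heat shock, jasmonate and suberin genes lay so near 0 that their sign flipped between scalings. Without the 0-1 mm library suberin (camera adjusted p = 0.000421) and wall loosening genes (camera adjusted p = 0.0270) went down with length. Of the 10 host lists that passed with camera for length, xylem, ethylene and phloem passed in fry and the others did not. With counts summed by description the ethylene, phloem, aquaporin and reference lists lost the call for length (camera adjusted p = 0.0990, 0.151, 0.0700 and 0.177). Over all unigenes 13 lists passed, and 0 did so with the estimated correlation.

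Single libraries were also set against each other without a test, to give the size of the steps along root growth. From 0-1 to 1-2 mm, 114 host unigenes were at least 4-fold higher and 137 lower, against 20 and 26 from 1-2 to 2-4 mm, 52 and 44 from 2-4 to 4-7 mm, and 28 and 18 from 4-7 to over 7 mm. At 8-fold this ranking turned, with 16 host unigenes from 0-1 to 1-2 mm and 21 from 2-4 to 4-7 mm. From bark to the 0-1, 1-2, 2-4, 4-7 and over 7 mm roots, 754, 518, 532, 629 and 703 host unigenes were higher and 905, 541, 754, 607 and 645 lower. Over all unigenes 5667, 4958, 5341, 5150 and 4787 were higher and 25715, 25719, 25841, 26109 and 25807 lower in the same order. Over all unigenes the steps between neighbouring root lengths had 138, 27, 57 and 102 higher and 648, 35, 187 and 18 lower.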

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

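The fits on host unigenes alone, and each alternative within them, were chosen after seeing the data, as were the set of best hits in Prunus only and the thinning of the root libraries, and the other alternatives were planned. No paired analysis was possible because each group has 1 library and the labels pair none. The number of unigenes higher in roots than in bark (12306) was 4775 with RLE scaling, 2222 with a filter of 10 counts in 2 libraries, 6156 in DESeq2, 934 in limma-voom, 18705 with log2(FPKM + 0.1), 4444 without non-plant hits, 4181 summed by description and 1511 for host unigenes alone. The number lower (58141) was 2948 with the filter, 3472 in limma-voom, 16987 without non-plant hits, 6947 summed and 1573 for host unigenes alone. With the root libraries thinned to the bark total, 10382 were higher and 58345 lower. Fewer units were tested with the filter, after summing and with organisms left out. The filter of 10 counts in 2 libraries drops unigenes with counts in bark alone. Of the fungal unigenes, 50122 had at least 10 counts in bark and 2270 had them in any root library. Beyond that the cause was not tested. Other settings moved these counts by less than 1.5 times. Host unigenes higher in roots (1511) came to 2297 in DESeq2, 144 in limma-voom, 779 summed, 641 without a length term, and between 139 and 2763 when leaving out each root library; the lower ones (1573) came to 602 in limma-voom, 996 summed, 1018 without a length term, and between 347 and 2408. The cause was not tested. In 2991 of the 3084 host calls DESeq2 gave the same direction past the threshold, and no host call turned round in DESeq2, limma-voom, the fit without a length term or any left-out library. For the length trend, 0 by edgeR, DESeq2 called 1404 rising and 1643 falling and limma-voom 720 and 752; among host unigenes DESeq2 called 693 rising and 957 falling, the lower bound in mm 2 falling, and leaving out each root library between 0 and 1813 rising and between 0 and 2127 falling, and the cause was not tested. In limma-voom 37836 unigenes had an unadjusted p under 0.05 for the trend. For roots against bark 23 lists passed over all unigenes, compared with a background mostly of other organisms. There 9 passed with an estimated correlation and 8 summed. Among host unigenes 9 passed, with 0 under an estimated correlation, 18 in fry and 3 summed. For length 13 lists passed over all unigenes, against 0 with an estimated correlation and between 8 and 13 on leaving out a root library, and among host unigenes 10 passed, with 0 under an estimated correlation, 3 in fry and 6 summed. The loss does not come from larger correlations in every list. The estimate lay under the preset 0.01 for host xylem (−0.0113), ethylene (−0.0133), phloem (−0.0289) and auxin transport genes (−0.00445). With an estimated correlation camera rests on the 3 residual degrees of freedom, and with a preset one on the number of genes. A list can therefore lose the call without a larger correlation. How much of the loss each accounts for was not tested. The host heat shock list pointed down in fry (adjusted p = 0.0188) and up in camera. Leaving out each root library, the host photosynthesis trend had an adjusted p between 8.60e-08 and 0.00951 and the host suberin trend between 0.000421 and 0.870, and both turned down without the 0-1 mm library (2.29e-06 and 0.000421). The cause was not tested. From bark to the 0-1, 1-2, 2-4, 4-7 and over 7 mm roots, FPKM gave 65328, 64135, 64567, 64806 and 64310 steps in place of 31382, 30677, 31182, 31259 and 30594, the 20 CPM minimum 10831, 10226, 10604, 10474 and 10241, and host unigenes alone 1659, 1059, 1286, 1236 and 1348. From 0-1 to 1-2 mm (786) the values were 73 at 8-fold, 261 at 20 CPM and 251 for host unigenes; from 1-2 to 2-4 mm (62) they were 10 at 8-fold, 106 with FPKM and 20 at 20 CPM; from 2-4 to 4-7 mm (244) they were 133, 67 and 96, and from 4-7 to over 7 mm (120) 24, 32 and 46, at 8-fold, at 20 CPM and for host unigenes. Fewer steps follow from a stricter limit. Between bark and the 0-1 mm roots, 77344 unigenes met the minimum of 5 with FPKM, against 42811 with CPM. From 1-2 to 2-4 mm 16954 met it with FPKM, against 17161 with CPM, and the cause was not tested for FPKM. Of the 78 named host genes past the threshold, 76 kept the call in DESeq2, 77 with RLE, 51 without a length term and 36 in limma-voom. Depth limits host genes in bark most, where 4484746 counts fell on host unigenes.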

Other observations

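In this part, the tests on organisms in the bark library, on scaling and on the exchange of libraries were chosen after the result was seen, as were the pathway counts and the genus shares. Some pathways of central carbon metabolism held more host unigenes higher in aerial roots than the other pathways did, although most of their members did not pass. Of 69 host unigenes of glyoxylate and dicarboxylate metabolism, which joins photorespiration to organic acids, 23 were higher in roots and 2 lower (Fisher's exact test over 114 pathways, adjusted p = 7.88e-06). In the citrate cycle 18 of 46 were higher and 3 lower (adjusted p = 7.88e-06) and in glycolysis 30 were higher, 24.4% of the set, and 6 lower (adjusted p = 8.09e-05). Plant-pathogen interaction had 27 of 193 host unigenes lower in roots (adjusted p = 0.00548), sesquiterpenoid and triterpenoid synthesis 7 of 20 (adjusted p = 0.00741), phenylpropanoid synthesis 18 of 119, with 18 others higher (adjusted p = 0.0131), and stilbenoid synthesis 6 of 21 (adjusted p = 0.0387). At an unadjusted p under 0.05 for the length trend, 22 of 56 unigenes of valine, leucine and isoleucine degradation had higher values in longer roots (adjusted p = 3.54e-07). Genes are not independent replicates in these tests.

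By best hit, the fungal unigenes of the bark library included those of Lophiotrema with 11.3% of its counts, Microthyrium with 8.76% and Diaporthe with 4.65%. A best hit does not identify the organism itself. The share of Fusarium, a genus of soil and plant fungi, was 0.0683, 0.134, 0.222, 0.0148 and 0.0138% in roots from the shortest to the longest, each within 0.025 percentage points at 95% (Wilson). Unigenes with domains found mostly in animals held 2459 CPM in bark and 999, 138, 69.5, 59.1 and 210 CPM in the roots. The value in the 0-1 mm roots was 7.25 times the highest of the 1-2, 2-4 and 4-7 mm roots, while the over 7 mm roots, with 210 CPM, were the next highest, so RNA of small animals may be present in the youngest roots.

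Far more unigenes were lower than higher in roots against bark. With the root libraries thinned to the bark total, a setting chosen after seeing the data, 10382 were higher and 58345 lower. Equal totals left the excess of lower calls, which argues against the difference in total depth. RNA of other organisms in the bark library may account for the lower calls, since 1.04% of them fell on host unigenes. Scaling over those organisms may account for the many host rises, since it moved the median log2 of host unigenes by 0.85. Whether the organisms lived in the bark or reached the sample later stays open.

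The length order of the roots was not singled out by the number of genes that follow it. Of the 60 orders of the 5 root libraries, 4, the labelled one included, gave as many unigenes at an unadjusted p under 0.05 as the labelled order did (6943, with 9467 the highest of the others), and 4 of 60 did so for host unigenes (5269, with 8353 the highest of the others), so chance is not excluded. In both sets, every order that gave more began with the 0-1 mm library and then the 2-4 mm library. Those orders share part of the labelled one, so the count of 4 does not measure chance alone. An exchange of the 1-2 and 2-4 mm libraries put 4479 host unigenes past the threshold, against at most 10 for any of the other orders. In the fit over all unigenes each of the 60 orders, this exchange included, put 0 past the threshold. There the same exchange had the most unigenes at an unadjusted p under 0.05 (9467). An exchange of these libraries could account for the weak trend among host unigenes. Bark tissue as sequenced, with its fungi, mixed into the 1-2 mm library is argued against by its Microthyrium share, which was 0.0715% of that in bark. Bark tissue without those fungi and a real departure of the 1-2 mm roots from a straight line stay open, and across host unigenes the 1-2 mm library had the highest Spearman correlation with bark (0.918, against 0.882 to 0.907 for the other roots).

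Ribosomal protein genes were lower in longer roots as a set at the preset correlation. They did not pass with an estimated correlation of 0.662 (camera adjusted p = 0.482) or in fry (adjusted p = 0.109), and the median slope was −0.21 per step. A bias with transcript length is argued against, since 0% of 10000 random lists matched on length and expression had a median slope as low. The 0-1 mm library alone is argued against, since the median slope without it was −0.15. A change with root length itself stays open, and no biological explanation was tested.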
